A study of Rattus norvegicus with 12 samples.

How the data were processed

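Gene expression was measured in terminal end buds, the growing duct tips of the immature mammary gland, cut out by laser microdissection from inbred female Sprague-Dawley rats. Newborn pups had received 1 injection of sesame oil alone or of diethylstilbestrol (DES, a synthetic estrogen) at 1 or 100 µg in oil, and glands were taken at 35 or 49 days of age. Each of the 6 groups has 2 animals and 2 arrays, so 12 arrays were analysed. With n = 2 arrays a group, precision is set by the number of arrays.

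Per the labels, amplified RNA from each sample was hybridized to a 1-colour Agilent rat array and read with Agilent Feature Extraction 9.1.3.1. The deposited value table holds the processed signal intensity of each array, with the background taken off and no scaling between arrays. It equals the signal in the scanner files of 10 arrays to within 0.497%. Scanner files of the 2 oil arrays at 49 days were not used here. In the authors' normalized table, each value is a ratio of a probe's signal to the array median, and then to the mean of that probe over the oil arrays at 35 days. Dividing the value table by array medians gave 99.99% of the detected values of that table to within 0.05 on the log2 scale. The authors' deposited tables of probes that differ at least 2-fold hold the linear fold of group means, DES over oil, with no test. The genome build is not given in the sources used here.

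The value table's intensities were divided by each array's median, floored at 0.01 and taken to the log2 scale. Of 20500 probes that are not controls, 13266 were called detected by the authors on both arrays of at least 1 group. Names came from the RefSeq gene table: 6547 probes were named by accession, 2451 by symbol, 693 by an older symbol and 74 by the symbol in the array file, while 10734 had no name. Where a gene had several probes, the brightest on average was kept, which was a choice among probes for 851 genes. This left 11859 genes and unnamed probes to test, 5635 of them with a gene symbol.

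The share of probes detected on both arrays was 60.4% for oil, 60.3% for DES 1 µg and 61.7% for DES 100 µg at 35 days. At 49 days it was 47.2%, 57.5% and 59.7%. Of the tested genes, 2903 were not detected on both oil arrays at 49 days, where the lowest detected signal was 1.04 and 1.03 of the array median against 0.214 to 0.368 on the other arrays. For a gene not above background in 1 group of a comparison, a size is given only as a lower bound taken from the lowest detected signal on the dim arrays.

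All arrays were fitted together in limma 3.58.1 (R 4.3.3) with a mean for each group, leaving 6 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, at a threshold of 0.05. Log2 differences are given with their standard error. Comparisons were each DES dose with oil at each age, the doses with each other at each age, the ages with each other within each treatment, and the change of each DES effect between the ages. On simulated data with 200 changed genes, this fit recovered 55% of 2-fold and 91% of 4-fold changes between DES 1 µg and oil at 35 days, and 9.88% of its 162 calls were false. For the change of the DES 1 µg effect between the ages it recovered 18% and 77%, with 3.06% of 98 calls false.

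Before the data were examined, 24 gene lists of at least 5 measured genes were fixed: estrogen-responsive genes, hormone receptors, luminal epithelium, basal and myoepithelium, milk and alveolar differentiation, cell cycle, duct growth factors and matrix remodelling, Wnt and Notch signalling, Hox and homeobox genes, DNA methylation and chromatin, DNA damage and p53, xenobiotic and estrogen metabolism, fatty acid and cholesterol synthesis, adipocyte, fibroblast and collagen matrix, endothelium, macrophage and antigen presentation, lymphocyte, mast cell and eosinophil, skeletal muscle, immediate early and stress, interferon response, ribosomal proteins, and mitochondrial oxidative phosphorylation. Shifts of fitted values, not of bounds, were tested with camera in limma at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The plan covered the DES and oil comparisons and age in oil, and list tests in the other comparisons were added after the data were seen. For each list the counts of genes that rose or fell use the adjustment over all genes, and counts adjusted over the list alone are given beside them.

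Named genes follow a rule set with the lists. For each DES dose and age they are the 8 largest rises and 8 largest falls, among genes with a symbol detected on both arrays of each group, that passed the test with both DES arrays beyond both oil arrays, and the 3 members with the smallest p of each list that passed. For dose, age and the change between ages they are the 4 largest rises and falls detected on both arrays of each group involved. Pgr, Prlr, Areg, Krt14 and Csn2 are given whatever their values, while Esr1, Gata3, Krt18 and Mki67, also on that list, were not among the tested genes.

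Chosen before the data were seen were scaling of the scanner signals by the 75th percentile, normexp background correction with an offset of 50 and quantile scaling on the scanner signals, quantile scaling of all 12 arrays, no filter on detection, detection on all 12 arrays, every probe on its own, a fit of the compared groups alone, a variance trend, the replicate number as a block, each array left out in turn, a 2-fold difference with no test, and, for lists, camera with an estimated correlation and fry. Normexp used the median spot signal of the scanner files, since the mean signal is not among their columns. Chosen after seeing the data were 75th percentile scaling of all 12 arrays, array signal as a covariate, scan day as a fixed or random block on 10 arrays, a floor of 0.3 and a fit without the dimmer arrays of 2 groups. Each array lay on a slide of its own, so slide could not serve as a block. The counts of named genes include 1 gene that is not reported here. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the tables, and matplotlib 3.10.9 drew the figures.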

Results

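Terminal end buds of rats given DES at birth were compared with those of oil controls at 35 and 49 days of age. There were 2 arrays from 2 animals in each of 6 groups, and 11859 genes and unnamed probes were tested. Genes for milk caseins, Csn1s2a and Csn2, rose strongly with DES 1 µg at 35 days, while interferon-induced genes were lower with both doses at that age than in oil. At 49 days the oil arrays differed from all others in signal as well as in expression, so comparisons with oil at that age carry this difference with them.

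The oil arrays at 49 days had a 75th percentile signal of 155 and 142.5, against 210 to 333 on the other 10 arrays, and they detected the fewest probes. Their lowest detected signal was 17.1 and 15.8, against 8.04 to 9.99 on the others, so detection there rests on a higher limit. On the first principal component, which held 41.4% of the variance, they scored 76.2 and 70.8, while the other arrays scored from -35.7 to 9.71. This score correlated with the log2 of the 75th percentile signal (r = -0.927, n = 12 arrays). Scan days are known for 10 arrays, with 2 arrays on each of 5 days, and not for these oil arrays. The scan day of oil at 49 days can therefore not be told apart from its treatment and age.

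**Figure D1:**
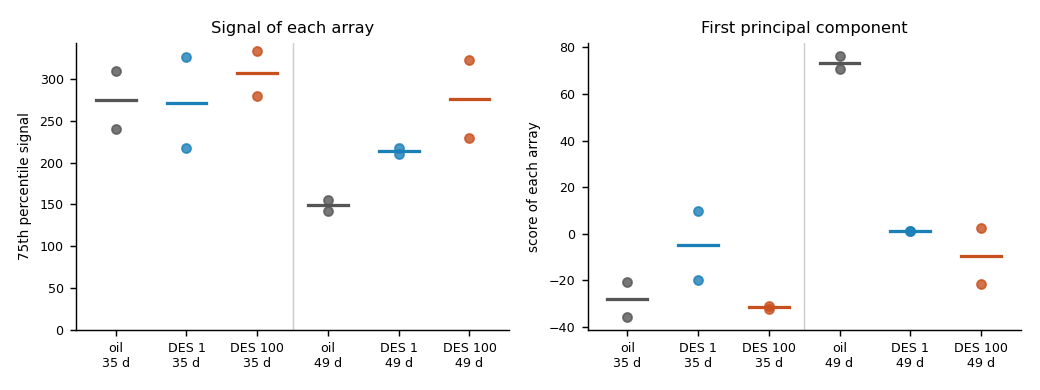
Signal and main axis of variation per array. Left, the 75th percentile of processed signal; right, the score on the first principal component, with 2 arrays in each of 6 groups.

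Milk protein genes gave the largest rises with DES 1 µg at 35 days. Csn1s2a and Csn2, which encode caseins, were 47.2-fold and 23.9-fold higher than in oil (log2 5.56 ± 0.25 and 4.58 ± 0.21, n = 2 arrays a group, adjusted p = 5.2e-05 for each). Glycam1, a mucin-like protein also secreted in milk, was at least 505.7-fold higher and not above background on either oil array (chosen after its values were seen). Clca1, a chloride channel regulator, rose by 3.82 ± 0.13, and Cd52, a surface glycoprotein of lymphocytes, by 2.72 ± 0.29. Fabp3, a fatty acid binding protein, rose by 2.49 ± 0.15 and the growth factor gene Igf2 by 2.40 ± 0.11. Sfrp2, a secreted modulator of Wnt signalling, rose by 2.32 ± 0.15. Across the milk and alveolar differentiation list, however, 5 of 19 measured genes rose, 5 fell and 9 did not pass (6 and 7 when adjusted over the list alone). Its median was -0.09 and its mean 0.82, and the list as a whole did not pass (camera adjusted p = 0.57).

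Among named genes detected on every array compared, Stc2, a secreted glycoprotein, fell most with DES 1 µg at 35 days (-4.12 ± 0.25, adjusted p = 0.00012). Gcnt3 and Fut2, which build glycans, fell as well (-3.84 ± 0.26 and -2.56 ± 0.30). So did Smim38 (-3.0 ± 0.22) and Pcp4, which binds calmodulin (-2.26 ± 0.15). Pgr, the progesterone receptor and a known target of estrogen, fell by less (-0.67 ± 0.11, adjusted p = 0.010). Values for Prlr (-0.32 ± 0.12, adjusted p = 0.16), Areg (-0.28 ± 0.13, adjusted p = 0.25) and Krt14 (0.13 ± 0.10, adjusted p = 0.49) did not pass. Of 14 estrogen-responsive genes 3 fell and none rose (1 rose and 3 fell over the list alone). The median of this list, -0.36, or -0.11 with undetected genes at their bounds, did not pass (adjusted p = 0.14). Counted over all genes, 376 rose and 504 fell.

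Genes induced by interferon fell as a group with DES 1 µg at 35 days. Of 17 measured in the interferon response list, 13 fell, none rose and 4 did not pass (16 fell over the list alone). Their median was -1.04 (camera adjusted p = 1.1e-15, and adjusted p = 0.026 with an estimated correlation). Ifit3 (-4.06 ± 0.44), the chemokine Cxcl10 (-3.88 ± 0.39) and Zbp1, a sensor of nucleic acids (-3.03 ± 0.21), fell. The transcription factor Irf7 fell too (-1.94 ± 0.14), as did Usp18, a protease for ISG15 (-1.78 ± 0.11). The macrophage and antigen presentation list moved with them, and 6 of its 17 genes fell (11 over the list alone). Among these were Fcgr3a (-1.26 ± 0.14), Cd74 (-1.03 ± 0.10) and RT1-DMa (-0.81 ± 0.13), and the median was -0.81 (adjusted p = 1.6e-06, and adjusted p = 0.026 with an estimated correlation). Lymphocyte genes did not pass as a list, with 1 of 11 higher, 5 lower and a median of -0.01 (adjusted p = 0.28).

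Markers of the stroma rose in the same arrays. In the endothelium list 8 of 12 genes rose and none fell (9 over the list alone), including Emcn (2.05 ± 0.15), Rasip1 (1.44 ± 0.15) and Pecam1 (1.25 ± 0.14). The endothelium median was 0.88 (adjusted p = 5.6e-08, and adjusted p = 0.072 with an estimated correlation). In the fibroblast and collagen matrix list 5 of 21 rose (9 over the list alone), such as Mgp (1.00 ± 0.13), Col1a2 (0.90 ± 0.19) and Bgn (0.68 ± 0.13). Its median was 0.47 (adjusted p = 6.2e-05, and adjusted p = 0.056 with an estimated correlation). The adipocyte list rose in 6 of 16 (8 higher and 2 lower over the list alone), with Cfd at 1.04 ± 0.20, Lpl at 0.84 ± 0.11 and Fabp4 at 0.73 ± 0.11. For adipocytes the median was 0.49 (adjusted p = 0.00088, and adjusted p = 0.16 with an estimated correlation). Among 6 genes of the mast cell and eosinophil list, Cma1 rose by 0.78 ± 0.18 and Mcpt1 was at least 2.13-fold higher, while Tpsb2 did not pass (0.35 ± 0.25, adjusted p = 0.44). That list had a median of 0.45 (adjusted p = 0.043, and adjusted p = 0.16 with an estimated correlation). Its call ended without oil array 1 or 2 or without DES array 1 (adjusted p = 0.085, 0.057 and 0.081).

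The fatty acid and cholesterol synthesis list fell, with 2 of 26 lower and none higher (7 over the list alone). The median was -0.34 (adjusted p = 0.00017, and adjusted p = 0.092 with an estimated correlation). Msmo1 (-0.84 ± 0.11) and Sc5d (-0.72 ± 0.13), enzymes of sterol synthesis, fell, and Sqle did not pass (-0.65 ± 0.17, adjusted p = 0.054). The cell cycle list rose: 6 of 36 genes were higher and 1 lower (7 and 2 over the list alone). Pttg1 (1.15 ± 0.15), Ndc80 (0.88 ± 0.18) and Plk1 (0.63 ± 0.13) were among them, and the median was 0.22 (adjusted p = 0.036, and adjusted p = 0.42 with an estimated correlation). Without oil array 2 or DES array 1 the cell cycle call ended (adjusted p = 0.19 and 0.20).

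Further lists did not pass between DES 1 µg and oil at 35 days. Their medians and adjusted p were 0.32 and 0.058 for skeletal muscle, -0.32 and 0.10 for luminal epithelium, and -0.17 and 0.11 for immediate early and stress. They were -0.11 and 0.28 for xenobiotic and estrogen metabolism, -0.02 and 0.36 for basal and myoepithelium, and -0.33 and 0.51 for duct growth factors and matrix remodelling. Ribosomal proteins stood at -0.06 and 0.52, hormone receptors at -0.14 and 0.55, and DNA damage and p53 at -0.12 and 0.55. DNA methylation and chromatin stood at 0.04 and 0.55, and mitochondrial oxidative phosphorylation at -0.01 and 0.77. For Hox and homeobox genes the median was 0.14 and the mean -0.08, and for Wnt and Notch signalling -0.12 and 0.01 (adjusted p = 0.94 for each).

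On the scan day that held 1 array of each group, Csn1s2a differed by 5.24, Csn2 by 4.61, Stc2 by -3.73 and Cxcl10 by -3.99. List medians on that day, and with scan day as a fixed block on 10 arrays, were -0.91 and -1.12 for interferon, -0.75 and -0.68 for macrophages, and 0.87 and 0.86 for endothelium. They were 0.34 and 0.42 for fibroblasts, 0.52 and 0.52 for adipocytes, 0.54 and 0.56 for mast cells, -0.34 and -0.41 for fatty acid synthesis and 0.14 and 0.19 for the cell cycle. Without oil array 1, oil array 2 or DES array 2 in turn, 342, 480 and 358 genes passed in place of 880. Of 38 named genes that passed, 28 did so without each array in turn, and the largest adjusted p reached on the way was 0.21, for Mcpt1 without DES array 2. Those that lost the call were Ndc80, Plk1, Sc5d, Cfd, Bgn, Col1a2, RT1-DMa, Cma1, Mcpt1 and Pgr, the last without oil array 1 or DES array 2 (adjusted p = 0.066 and 0.052). With 75th percentile scaling of all 12 arrays the split was 567 higher and 506 lower.

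**Figure D2:**
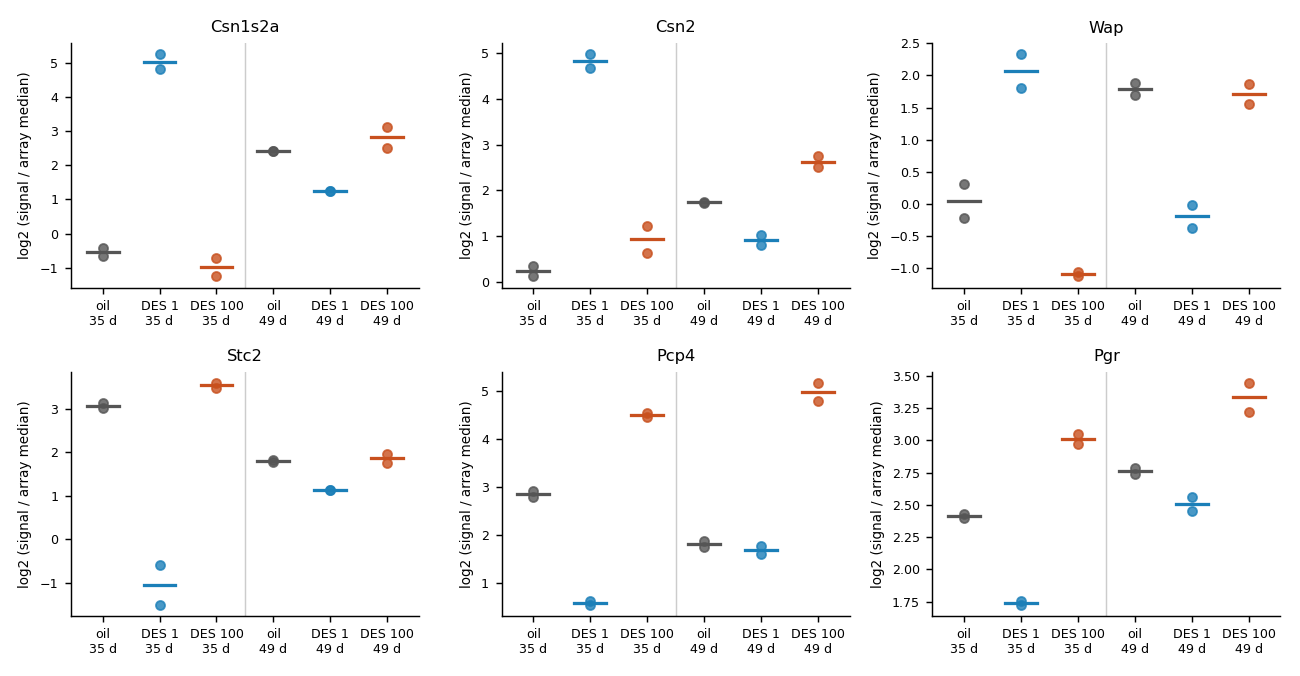
Signal of 6 genes on each array, log2 relative to the array median. Caseins Csn1s2a and Csn2, Wap, Stc2, Pcp4 and Pgr are shown for 2 arrays in each of 6 groups.

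With DES 100 µg at 35 days far fewer genes passed, 48 higher and 104 lower, and the largest falls among named genes detected on every array compared were in genes of the interferon response. Cxcl10 fell by 4.65 ± 0.39 and Ifit3 fell by 4.41 ± 0.44 on the log2 scale (n = 2 arrays a group, adjusted p = 0.0019 and 0.0028). The chemokine gene Ccl7 (-2.5 ± 0.17), Irf7 (-1.97 ± 0.14), Zbp1 (-1.82 ± 0.21) and Usp18 (-1.79 ± 0.11) fell too, as did Il2rb, an interleukin 2 receptor (-1.75 ± 0.16), and Ifgga2l1 (-1.65 ± 0.14). The interferon response list had 9 of 17 genes lower and none higher (16 over the list alone). Its median was -0.93 (camera adjusted p = 1.3e-26, and adjusted p = 0.0052 with an estimated correlation). In the macrophage and antigen presentation list 4 of 17 fell (8 over the list alone), among them Fcgr3a (-1.56 ± 0.14), Ccl6 (-0.93 ± 0.11) and Cd74 (-0.77 ± 0.10). The macrophage median was -0.69 (adjusted p = 6.4e-13, and adjusted p = 0.0052 with an estimated correlation).

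Lymphocyte genes fell as well with DES 100 µg at 35 days, 2 of 11 in number (6 over the list alone). Jchain, the joining chain of antibodies (-1.61 ± 0.18), and the T cell gene Cd3g (-1.24 ± 0.19) fell, and Zap70 did not pass (-0.98 ± 0.21, adjusted p = 0.078). The lymphocyte median was -0.64 (adjusted p = 4.9e-06, and adjusted p = 0.016 with an estimated correlation). In the interferon, macrophage and lymphocyte lists both DES arrays lay below both oil arrays. Of 36 list calls in the planned comparisons 5 held with an estimated correlation: these 3, and the interferon and macrophage lists with DES 1 µg.

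Among named genes detected on every array compared, the largest rises with DES 100 µg at 35 days were in Rgs4, a regulator of G protein signalling (2.21 ± 0.21, adjusted p = 0.0026), Tfpi, an inhibitor of blood coagulation (1.91 ± 0.24), and Pcp4 (1.65 ± 0.15). Next came the calcium sensor Vsnl1 (1.44 ± 0.25), Pdlim3 (1.41 ± 0.13), Lrat, which esterifies retinol (1.40 ± 0.17), Serpinb6b (1.20 ± 0.13) and the kinase gene Clk1 (1.08 ± 0.15). Pgr was higher (0.60 ± 0.11, adjusted p = 0.049), where with DES 1 µg it had fallen. Csn2 did not pass (0.69 ± 0.21, adjusted p = 0.22), and neither did Prlr (-0.28 ± 0.12), Areg (-0.04 ± 0.13) or Krt14 (0.01 ± 0.10).

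Further lists passed with DES 100 µg at 35 days at larger p. In fibroblast and collagen matrix Ogn (-0.81 ± 0.15) and Mgp (-0.69 ± 0.13) fell, 2 of 21 genes with either adjustment, and Mfap5 did not pass (-0.50 ± 0.21). Its median was -0.18 (adjusted p = 0.046, and adjusted p = 0.24 with an estimated correlation). No single gene passed in 3 further lists. Fatty acid and cholesterol synthesis had a median of -0.14 (adjusted p = 0.0045, and adjusted p = 0.21 with an estimated correlation), with Msmo1 at -0.56, Fdft1 at -0.50 and Mvd at -0.51. Mast cell and eosinophil had a median of 0.40 (adjusted p = 0.046, and adjusted p = 0.21 with an estimated correlation), with Mcpt1 (adjusted p = 0.11), Cma1 at 0.44 and Cpa3 at 0.71. The cell cycle had a median of 0.25 (adjusted p = 0.046, and adjusted p = 0.48 with an estimated correlation), with Dlgap5 at 0.56, Cenpe at 0.55 and Rrm1 at 0.55. Hox and homeobox genes, with a median of -0.38 and a mean of 0.02, did not pass (adjusted p = 0.23). Adjusted over the list alone, 1 gene of the fatty acid list fell and 1 of the mast cell list rose. The cell cycle call ended without oil array 2 (adjusted p = 0.32) or DES array 1 or 2 (adjusted p = 0.096 and 0.11), and the fatty acid call without oil array 1 (adjusted p = 0.057). Without oil array 1 or DES array 1 the fibroblast call ended (adjusted p = 0.16 and 0.11), as did the mast cell call (adjusted p = 0.19 and 0.17). The mast cell call also ended without DES array 2 (adjusted p = 0.053).

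No scan day held an array of DES 100 µg and one of oil at 35 days. With scan day as a fixed block the medians were -1.05 for the interferon list, -0.46 for macrophages, -0.73 for lymphocytes and 0.34 for the cell cycle, and these 4 calls held. The calls of fatty acid synthesis, fibroblasts and mast cells ended, at medians of -0.22, -0.11 and 0.24 (adjusted p = 0.17, 0.42 and 0.15). Leaving out oil array 1, oil array 2, DES array 1 or DES array 2 gave 53, 52, 75 and 65 genes in place of 152. Of 24 named genes 12 passed throughout, and Pgr reached an adjusted p of 0.28 without DES array 1. The others that lost the call were Tfpi, Vsnl1, Lrat, Clk1, Zbp1, Ogn, Mgp, Ccl6, Cd74, Jchain and Cd3g. The calls of Ogn and Mgp also ended with array signal as a covariate.

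Between the doses at 35 days, Stc2 was 24.1-fold, Gcnt3 16.8-fold, Rgs4 16-fold and Pcp4 15-fold higher with DES 100 µg than with DES 1 µg (log2 4.59 ± 0.25, 4.07 ± 0.26, 4.0 ± 0.21 and 3.91 ± 0.15, n = 2 arrays a group). The milk protein genes went the other way, with Csn1s2a at -6.01 ± 0.25, Csn2 at -3.88 ± 0.21 and Wap, whey acidic protein, at -3.17 ± 0.24, as did Clca1 at -4.60 ± 0.13. Pgr was higher with the larger dose (1.27 ± 0.11, adjusted p = 0.00043), and Prlr (0.04), Krt14 (-0.12) and Areg (0.24) did not pass. In all, 491 genes were higher and 455 lower.

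Stromal lists were lower with DES 100 µg than with DES 1 µg at 35 days. Endothelium was lower in 9 of 12 genes (10 over the list alone), with a median of -1.30 (camera adjusted p = 3.1e-10, and adjusted p = 0.075 with an estimated correlation). Fibroblast and collagen matrix was lower in 8 of 21 and higher in 1 (12 and 2 over the list alone). Its median was -0.55 (adjusted p = 3e-06, and adjusted p = 0.075 with an estimated correlation). The adipocyte list was lower in 7 of 16 and higher in 2 (8 and 3), and its median was -0.61 (adjusted p = 0.0094, and adjusted p = 0.43 with an estimated correlation). Immediate early and stress genes were higher in 6 of 26 and lower in 1 (8 and 1), with a median of 0.34 (adjusted p = 0.032, and adjusted p = 0.50 with an estimated correlation). The immediate early and stress call ended without DES 1 µg array 1 or DES 100 µg array 2 (adjusted p = 0.22 and 0.080), and the adipocyte call without the latter (adjusted p = 0.062).

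On the scan day shared by both doses at 35 days the medians were -1.40 for endothelium, -0.50 for fibroblasts and -0.54 for adipocytes, and with scan day as a fixed block -1.35, -0.45 and -0.52. That block ended the immediate early and stress call (median 0.26, adjusted p = 0.19). All 9 named genes that passed between the doses did so without each array in turn. Without DES 1 µg array 2, DES 100 µg array 1 or DES 100 µg array 2, 441, 472 and 463 genes passed in place of 946.

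At 49 days, the largest rises with DES 1 µg over oil, among named genes detected on every array compared, included the immediate early genes Ier3 and Ccn1. Ier3 was 8.96-fold, Gadd45g 7.60-fold and Ccn1 6.10-fold higher (log2 3.16 ± 0.14, 2.93 ± 0.19 and 2.61 ± 0.14, n = 2 arrays a group, adjusted p = 4.4e-05, 0.00014 and 9.9e-05). Hpgd, which degrades prostaglandins, rose by 2.54 ± 0.29, Cd52 by 2.22 ± 0.29 and Plat, tissue plasminogen activator, by 2.15 ± 0.31. The stress factor gene Atf3 rose by 2.13 ± 0.12 and Colec12, a scavenger receptor, by 1.94 ± 0.32. Of 26 genes in the immediate early and stress list 11 rose and 3 fell (13 and 3 over the list alone). Its median was 0.43 (camera adjusted p = 4.5e-05, and 0.16 with an estimated correlation) and 0.35 with undetected genes at their bounds. In this comparison 1507 genes rose and 2262 fell. Of these, 850 were not detected on both arrays of both groups, and the direction of some is not established.

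Milk genes fell with DES 1 µg at 49 days, the reverse of the caseins at 35 days. Wap (-1.98 ± 0.24), Csn3 (-1.57 ± 0.24), Lalba, a subunit of lactose synthase (-1.07 ± 0.15), and Csn2 (-0.82 ± 0.21) fell. In the milk and alveolar differentiation list 10 of 19 fell and 1 rose (the same over the list alone). The milk median was -0.49 (adjusted p = 0.016, and adjusted p = 0.37 with an estimated correlation), and without oil array 2 the call ended (adjusted p = 0.059). Fatty acid and cholesterol synthesis fell with 12 of 26 genes lower and 1 higher (13 and 1 over the list alone), such as Sqle (-1.38 ± 0.17), Fdft1 (-1.07 ± 0.13) and Lss (-0.83 ± 0.11). Its median was also -0.49 (adjusted p = 0.0021, and adjusted p = 0.17 with an estimated correlation). With undetected genes at their bounds the medians were -0.51 for milk and -0.53 for fatty acid synthesis.

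Among named genes detected on every array compared, the largest single falls with DES 1 µg at 49 days had wide errors. They were in Fxyd7 (-4.32 ± 1.28), Glycam1 (-3.06 ± 0.91), the homeobox genes Dlx3 (-3.01 ± 0.70) and Hoxb2 (-2.84 ± 0.61), and the matrix protein gene Ecm1 (-2.95 ± 0.61). Caskin1 (-2.86 ± 0.56), Ccdc33 (-2.75 ± 0.47) and Pianp (-2.70 ± 0.52) followed. Pgr (-0.26 ± 0.11, adjusted p = 0.11), Prlr (0.28 ± 0.12), Krt14 (0.23 ± 0.10) and Areg (0.10 ± 0.13) did not pass.

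Stromal markers were higher with DES 1 µg than in oil at 49 days. The adipocyte list rose in 13 of 16 genes (14 higher and 1 lower over the list alone), with Fabp4 at 1.86 ± 0.11, Adipoq at 1.74 ± 0.16 and Slc2a4 at least 1.30-fold higher. Its median was 0.93 (adjusted p = 1.6e-07, and 0.080 with an estimated correlation) and 0.85 at the bounds. Fibroblast and collagen matrix genes rose in 14 of 21 and fell in 1 (15 and 2 over the list alone), such as Ogn (1.89 ± 0.15), Mgp (1.31 ± 0.13) and Vim (1.25 ± 0.14). The fibroblast median was 0.90 (adjusted p = 4.5e-05, and 0.080 with an estimated correlation) and 0.45 at the bounds. In endothelium 6 of 12 rose and 2 fell with either adjustment, among them Emcn (1.51 ± 0.15) and Pecam1 (1.21 ± 0.14). For Cldn5, counted by its fit, neither size nor direction is established. The median was 0.61 (adjusted p = 0.022, and 0.41 with an estimated correlation) and 0.39 at the bounds.

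Mast cell and macrophage markers moved in the same direction, while the lymphocyte and interferon response lists did not pass (medians -0.21 and -0.23, or -0.31 and -0.28 at the bounds, adjusted p = 0.88 and 0.40). Of 6 mast cell and eosinophil genes 4 rose with DES 1 µg at 49 days, with Cpa3 at least 9.17-fold higher, Cma1 at 1.66 ± 0.18 and Tpsb2 at least 1.03-fold higher. Their median was 1.43 (adjusted p = 0.013, and 0.16 with an estimated correlation) but 0.04 at the bounds. Macrophage and antigen presentation had 3 of 17 higher and 1 lower with either adjustment, Fcgr2b (0.61 ± 0.10) and C1qb (0.66 ± 0.17) among the rises. Cybb is counted by its fit, but it lies below the detection limit of the oil arrays and its direction is not established. The median was 0.31 (adjusted p = 0.045, and 0.24 with an estimated correlation) but 0.08 at the bounds. Without oil array 2 the calls of endothelium and of macrophage and antigen presentation ended (adjusted p = 0.070 and 0.11), and without DES array 2 the macrophage call (adjusted p = 0.15).

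Housekeeping lists, which rose with age in oil, fell with DES 1 µg at 49 days. For mitochondrial oxidative phosphorylation 14 of 39 fell and 1 rose (16 and 1 over the list alone), among them Atp5mc1 (-1.46 ± 0.21), Cox5a (-1.17 ± 0.19) and Cox5b (-0.74 ± 0.12). Its median was -0.40 (adjusted p = 0.00045, and adjusted p = 0.34 with an estimated correlation). Ribosomal proteins fell in 8 of 37 (2 over the list alone), including Rps26 (-2.17 ± 0.27), Rpl18 (-0.89 ± 0.23) and Rpl29 (-0.73 ± 0.11). The ribosomal median was -0.49 (adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation). Quantile scaling ended both calls (adjusted p = 0.079 and 0.84), and without oil array 2 the ribosomal call ended (adjusted p = 0.059).

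Dependence on single arrays was large at 49 days. Between DES 1 µg and oil 3769 genes passed, and 1543, 2177, 1608 and 1993 without oil array 1, oil array 2, DES array 1 and DES array 2. Of 44 named genes 33 passed throughout, and Fxyd7 reached an adjusted p of 0.15 without DES array 1. The others that lost the call were Glycam1, Dlx3, Ecm1, Caskin1, Hoxb2, Pianp, C1qb, Tpsb2, Rpl18 and Csn2, so 7 of the 8 largest falls did so. Csn2 lost it without each of the 4 arrays (adjusted p = 0.085, 0.078, 0.11 and 0.052). With array signal as a covariate those of Fxyd7, C1qb and Rpl18 ended. The split of 1507 higher and 2262 lower became 1987 and 1741 with 75th percentile scaling, 1880 and 1522 with quantile scaling, and 990 and 2394 among genes detected on all 12 arrays.

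With DES 100 µg at 49 days, Pcp4 was 9.05-fold, Plat 7.70-fold and Atf3 5.09-fold higher than in oil (log2 3.18 ± 0.15, 2.94 ± 0.31 and 2.35 ± 0.12, n = 2 arrays a group, adjusted p = 3.1e-05, 0.0012 and 4.9e-05). Aadat, an aminotransferase, rose by 2.03 ± 0.22, Hpgd by 1.97 ± 0.29 and Prelid3b by 1.82 ± 0.32. The fatty acid transporter Cd36 rose by 1.70 ± 0.22 and the calcium channel gene Trpc6 by 1.66 ± 0.21. Falls among named genes detected on every array compared were led by Glycam1 (-6.11 ± 0.91), Foxe1 (-4.13 ± 1.13), Irf2bpl (-3.76 ± 0.95) and Pitpnm1 (-3.39 ± 0.91). Pianp (-3.39 ± 0.52), Cldn14 (-3.37 ± 0.93), Slc13a3 (-3.31 ± 0.12) and Ecm1 (-3.12 ± 0.61) fell too. Pgr rose (0.57 ± 0.11, adjusted p = 0.0099) and so did Csn2 (0.88 ± 0.21, adjusted p = 0.019), while Areg (0.20 ± 0.13) and Krt14 (-0.26 ± 0.10) did not pass. In total 1302 genes rose and 1694 fell, 816 of them not detected on both arrays of both groups and some with no established direction.

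Among milk and alveolar differentiation genes 8 of 19 rose and 2 fell with DES 100 µg at 49 days (9 and 2 over the list alone). Aqp5, a water channel, rose by 1.26 ± 0.14, Xdh, an enzyme of milk fat secretion, by 0.86 ± 0.10 and Stat5a, which carries the prolactin signal, by 0.73 ± 0.11. The list median was 0.41, 0.32 at the bounds, and the mean 0.03 (camera adjusted p = 0.015, and adjusted p = 0.42 with an estimated correlation). Without oil array 1 or DES array 2 the milk call ended (adjusted p = 0.085 and 0.080). Duct growth factors and matrix remodelling rose in 6 of 26 and fell in 3 with either adjustment, with Plat and Tgfb3 (0.90 ± 0.16). For Erbb3, counted by its fit, the direction is not established. Its median was 0.43 (adjusted p = 0.018, and 0.32 with an estimated correlation) but 0.10 at the bounds. With no filter on detection the duct growth call ended (adjusted p = 0.092).

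Adipocyte genes rose in 8 of 16 and fell in 1 with DES 100 µg at 49 days (9 and 1 over the list alone), including Cd36 and Fabp4 (0.87 ± 0.11). For Slc2a4, counted by its fit, neither size nor direction is established. The adipocyte median was 0.53 (adjusted p = 0.00067, and 0.32 with an estimated correlation) and 0.31 at the bounds. In fibroblast and collagen matrix 5 of 21 rose and 1 fell with either adjustment, with Col5a1 at 1.18 ± 0.23, Vim at 0.97 ± 0.14 and Loxl1 at 0.82 ± 0.19. Its median was 0.38 (adjusted p = 0.034, and 0.32 with an estimated correlation) and 0.15 at the bounds. The fibroblast call ended without oil array 1, oil array 2 or DES array 2 (adjusted p = 0.085, 0.071 and 0.095).

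Against the same oil arrays, the housekeeping lists were lower with DES 100 µg at 49 days as well, with the same limit of RNA quality. Mitochondrial oxidative phosphorylation fell in 18 of 39 genes (20 over the list alone), such as Cox7a2 (-1.18 ± 0.19), Cox5b (-0.91 ± 0.12) and Atp5po (-0.72 ± 0.11). The mitochondrial median was -0.58 (adjusted p = 1.5e-05, and adjusted p = 0.32 with an estimated correlation). Ribosomal proteins fell in 17 of 37 (18 lower and 1 higher over the list alone), including Rps26 (-2.27 ± 0.27), Rpl29 (-0.52 ± 0.11) and Rps6, which was saturated on 10 arrays and is given no size. Their median was -0.52 (adjusted p = 9.4e-05, and adjusted p = 0.40 with an estimated correlation). Quantile scaling ended the ribosomal call (adjusted p = 0.22), and array signal as a covariate ended it and the mitochondrial call (adjusted p = 0.23 and 0.071).

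Without oil array 1, oil array 2 or DES array 1, 1234, 1499 and 1168 genes passed between DES 100 µg and oil at 49 days in place of 2996, and 2473 without DES array 2. Of 34 named genes 23 passed throughout, with Pitpnm1 at an adjusted p of 0.17 without DES array 1, and 14 passed with array signal as a covariate. Foxe1, Irf2bpl, Cldn14, Ecm1, Col5a1, Loxl1, Rpl29 and Rps6 also lost the call without an array, and with the covariate as well. The covariate further ended those of Hpgd, Prelid3b, Cd36, Pianp, Erbb3, Tgfb3, Vim, Atp5po and Cox7a2, and turned Pitpnm1 to 0.11 (adjusted p = 0.89). The Csn2 call ended without oil array 1, oil array 2 or DES array 1 (adjusted p = 0.086, 0.073 and 0.11), and that of Pgr without oil array 1 or 2 (adjusted p = 0.050 and 0.058). The covariate ended both, with Csn2 at 0.33 and Pgr at 0.67 (adjusted p = 0.46 and 0.075). The split of 1302 and 1694 became 1709 higher and 1234 lower with 75th percentile scaling, 1554 and 1182 with quantile scaling, and 777 and 1792 among genes detected on all 12 arrays.

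Both doses share oil arrays, which alone correlates their differences from oil. At 35 days 13 genes were higher and 60 lower with both doses, and 9 and 12 went opposite ways. Ignoring the shared arrays, independent calls would give 1.52 and 4.42 in common. At 49 days 815 were higher and 1154 lower with both, against 165 and 323, and 14 and 19 went opposite ways. The differences correlated across genes at 0.271 at 35 and 0.784 at 49 days. Data simulated with shared oil arrays and no DES effect gave 0.503 and 0.50. No offset of oil arrays was simulated, so DES cannot be told from one. The 49-day differences correlated with age in oil at -0.770 and -0.856 (simulated -0.50).

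**Figure D3:**
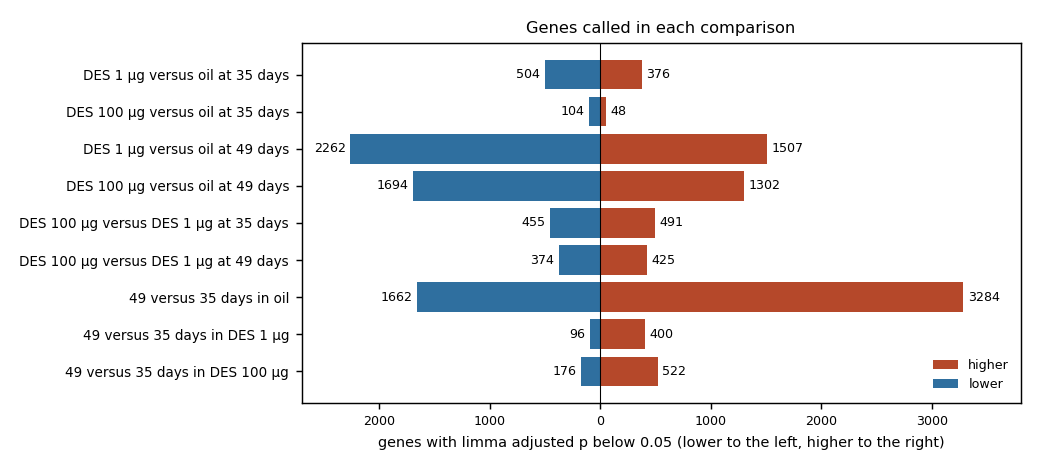
Genes that passed the test in 9 comparisons, higher and lower. Each comparison is between groups of 2 arrays.

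Milk genes were higher with DES 100 µg than with DES 1 µg at 49 days, the opposite of the caseins at 35 days. In the milk and alveolar differentiation list 12 of 19 were higher and none lower (15 and 2 over the list alone), Csn2 by 1.71 ± 0.21 (n = 2 arrays a group). The milk median was 0.85 (camera adjusted p = 1.7e-09, and adjusted p = 0.076 with an estimated correlation). Named genes detected on every array of both doses that differed most were Pcp4 (9.84-fold, log2 3.30 ± 0.15), Vsnl1 (7.99-fold), Gcnt3 (5.92-fold) and Lypd1 (5.21-fold) on the higher side. On the lower side were Cd52 (-4.45 ± 0.29), Acsm3 (-2.59 ± 0.12), Slc13a3 (-2.37 ± 0.12) and Slc22a7 (-2.24 ± 0.27). Pgr was higher (0.83 ± 0.11, adjusted p = 0.0052) and Krt14, a basal keratin, lower (-0.49 ± 0.10, adjusted p = 0.028), while Prlr (-0.28) and Areg (0.11) did not pass. In total 425 genes were higher and 374 lower.

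Fatty acid and cholesterol synthesis was higher with DES 100 µg than with DES 1 µg at 49 days in 6 of 26 genes (10 over the list alone). Its median was 0.37 (adjusted p = 0.00017, and adjusted p = 0.076 with an estimated correlation). Duct growth factors and matrix remodelling was higher in 3 of 26, with a median of 0.40 (adjusted p = 0.032, and 0.22 with an estimated correlation) and 0.26 at the bounds. Stromal lists were lower, adipocyte in 5 of 16 genes (9 over the list alone), with a median of -0.49 (adjusted p = 2.2e-05, and adjusted p = 0.076 with an estimated correlation). Fibroblast and collagen matrix was lower in 3 of 21 (4), with a median of -0.43 (adjusted p = 0.00017, and adjusted p = 0.076 with an estimated correlation). Endothelium was lower in 3 of 12 (5), with a median of -0.46 (adjusted p = 0.00040, and adjusted p = 0.17 with an estimated correlation).

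The mast cell and eosinophil list was lower with DES 100 µg in 2 of 6 genes (3 over the list alone). Its median was -1.02 (adjusted p = 0.0025, and 0.076 with an estimated correlation) and -1.24 at the bounds. Macrophage and antigen presentation was lower in 3 of 17 (3), with a median of -0.32 (adjusted p = 0.0029, and adjusted p = 0.076 with an estimated correlation). Immediate early and stress genes were lower in 8 of 26 and higher in 1 (10 and 2), with a median of -0.33 (adjusted p = 0.00012, and adjusted p = 0.11 with an estimated correlation). Cell cycle genes were lower in 2 of 36 and higher in 1, with a median of -0.37 (adjusted p = 0.028, and adjusted p = 0.40 with an estimated correlation). Ribosomal proteins were lower in 2 of 37, with a median of -0.14 (adjusted p = 0.027, and adjusted p = 0.46 with an estimated correlation). Quantile scaling ended the ribosomal call (adjusted p = 0.25), and a fixed scan-day block ended it and that of duct growth factors and matrix remodelling (adjusted p = 0.10 and 0.47). Array signal as a covariate ended the same 2 calls (adjusted p = 0.81 and 0.11).

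On the scan day shared by both doses at 49 days, and with scan day as a fixed block, the medians were 1.01 and 0.92 for milk genes, 0.36 and 0.44 for fatty acid synthesis and -0.38 and -0.39 for adipocytes. They were -0.35 and -0.39 for fibroblasts, -0.35 and -0.37 for endothelium, -1.08 and -1.0 for mast cells, -0.45 and -0.44 for macrophages and -0.16 and -0.18 for immediate early genes. Without DES 1 µg array 1 or 2, or DES 100 µg array 1 or 2, 255, 287, 522 and 248 genes passed in place of 799. Of 11 named genes Krt14 alone was lost (largest adjusted p = 0.15). The cell cycle call ended without DES 1 µg array 2 or DES 100 µg array 2 (adjusted p = 0.072 and 0.056). That of duct growth factors and matrix remodelling ended without DES 1 µg array 1 or DES 100 µg array 1 (adjusted p = 0.10 and 0.16), and that of ribosomal proteins without DES 1 µg array 2 or DES 100 µg array 1 (adjusted p = 0.074 and 0.42).

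**Figure D4:**
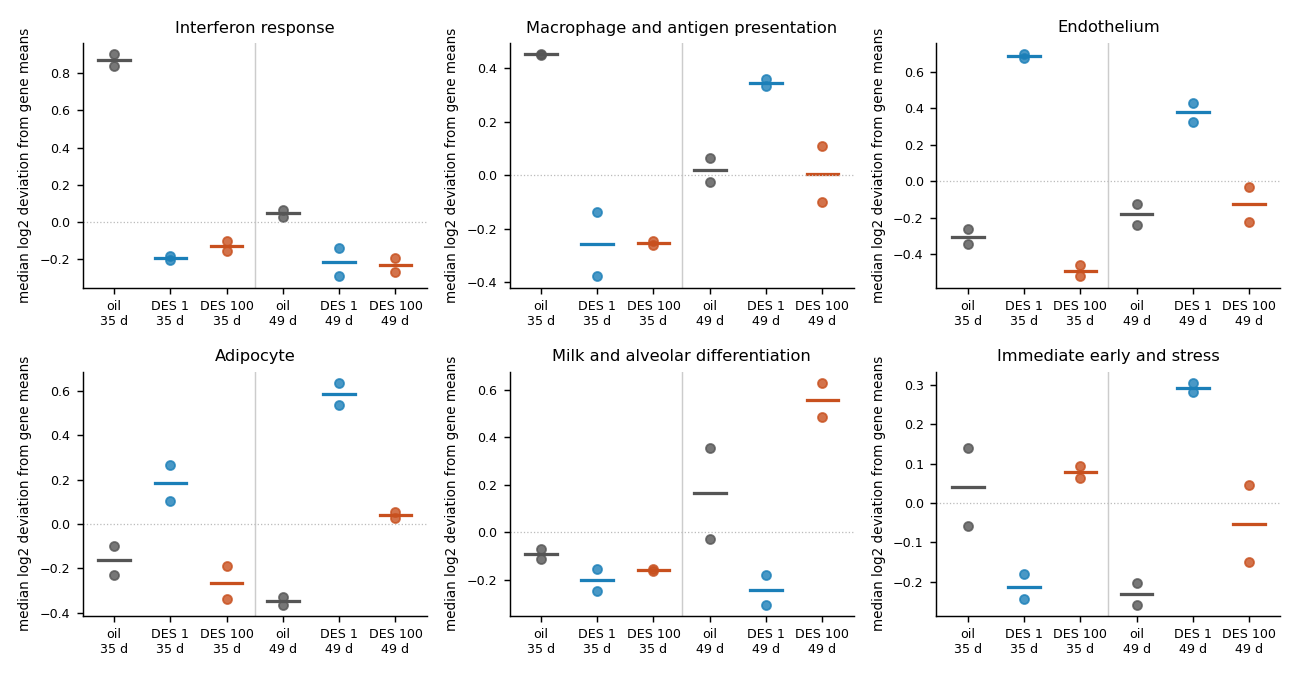
Median log2 deviation from gene means in 6 gene lists on each array. Groups of 2 arrays are set side by side by treatment and age.

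In oil 3284 genes were higher and 1662 lower at 49 than at 35 days. This is the largest count of any comparison, but with array signal as a covariate 1027 genes passed, fewer than the 2061 of DES 1 µg at 49 days. Igf2 rose 12.1-fold (log2 3.59 ± 0.11, n = 2 arrays a group, adjusted p = 8e-06) and Csn2 2.83-fold (1.50 ± 0.21). Glycam1 was at least 161.9-fold higher (chosen after its values were seen). Fxyd7 (4.35 ± 1.28), Pitpnm1 (3.37 ± 0.91) and Tcf3 (3.1 ± 0.56) rose with wide errors, and for Tcf3 another probe passed with the opposite sign. Array signal as a covariate turned Fxyd7 to -0.42 and Pitpnm1 to -0.15 and left Tcf3 at 1.1 (adjusted p = 0.73, 0.82 and 0.14), so their direction is not settled. Interferon-induced genes were among the largest falls of named genes detected on every array of both ages, with Ubd at -2.16 ± 0.11, Gbp2 at -2.14 ± 0.21 and Irf7 at -2.03 ± 0.14, beside Hpgd at -2.73 ± 0.29. Areg, an estrogen-induced factor of duct growth, rose by 0.53 ± 0.13 (adjusted p = 0.014) and Pgr by 0.35 ± 0.11 (adjusted p = 0.038). Quantile scaling ended both calls, with Areg at 0.07 and Pgr at 0.23 (adjusted p = 0.67 and 0.096). Prlr (-0.04) and Krt14 (-0.06) did not pass.

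The interferon response list fell with age in oil in 11 of 17 genes, with none higher and the same counts over the list alone. Its median was -0.89 with or without bounds (camera adjusted p = 9.1e-09, and adjusted p = 0.18 with an estimated correlation). Macrophage and antigen presentation fell in 7 of 17 and rose in 1 with either adjustment. Its median was -0.39 (adjusted p = 0.013, and 0.28 with an estimated correlation) but -0.07 at the bounds. Immediate early and stress fell in 8 of 26 and rose in 3 with either adjustment. Its median was -0.11 (adjusted p = 0.034, and 0.48 with an estimated correlation) but -0.02 at the bounds. Ribosomal proteins rose in 19 of 37 with either adjustment, with a median of 0.60 (adjusted p = 0.013, and adjusted p = 0.49 with an estimated correlation). Mitochondrial oxidative phosphorylation rose in 18 of 39 (19 over the list alone), with a median of 0.42 (adjusted p = 0.013, and adjusted p = 0.49 with an estimated correlation). Quantile scaling ended the ribosomal and mitochondrial calls (adjusted p = 0.97 and 0.47), and they also ended without oil array 1 of 35 days (adjusted p = 0.071 and 0.051). The immediate early call ended without that array or without oil array 1 of 49 days (adjusted p = 0.051 and 0.050), and the macrophage call without oil array 2 of 35 days (adjusted p = 0.061).

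Over all tested genes the median shift with age in oil was 0.157 with division by the array median and 0.007 with the 75th percentile. The split of 3284 higher and 1662 lower became 2296 and 2318 with that scaling, 2064 and 2226 with quantile scaling and 3256 and 942 among genes detected on all 12 arrays. Without oil array 1 of 35 or of 49 days 2859 and 2718 genes passed in place of 4946. Of 11 named genes 7 passed throughout, with Pgr at an adjusted p of 0.16 without oil array 1 of 49 days. Fxyd7, Pitpnm1 and Areg lost the call too, and the covariate ended those of Areg and Pgr (adjusted p = 0.18 and 0.34).

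With DES 1 µg, the milk protein genes fell between 35 and 49 days. Csn2 (-3.90 ± 0.21, n = 2 arrays a group), Csn1s2a (-3.78 ± 0.25), Wap (-2.26 ± 0.24) and Glycam1 (-4.71 ± 0.91) were lower. Of named genes detected on every array of both ages, rises were largest in Acsm3 (2.93 ± 0.12), Padi2 (2.33 ± 0.11), Msln (2.29 ± 0.21) and Stc2 (2.19 ± 0.25). Areg rose by 0.91 ± 0.13, Pgr by 0.76 ± 0.11 and Prlr by 0.56 ± 0.12 (adjusted p = 0.0099, 0.010 and 0.044), and Krt14 (0.04) did not pass. In all 400 genes rose and 96 fell.

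Estrogen-responsive genes rose with age under DES 1 µg in 4 of 14 (5 over the list alone). Their median was 0.55 (camera adjusted p = 0.0029, and 0.27 with an estimated correlation) and 0.35 at the bounds. Immediate early and stress rose in 11 of 26 (15), with a median of 0.57 (adjusted p = 4e-06, and adjusted p = 0.18 with an estimated correlation). Macrophage and antigen presentation rose in 3 of 17 (8), with a median of 0.63 (adjusted p = 3.2e-05, and 0.086 with an estimated correlation) and 0.57 at the bounds. The adipocyte list rose in 2 of 16, with a median of 0.38 (adjusted p = 0.0017, and adjusted p = 0.27 with an estimated correlation). Endothelium fell in 3 of 12, with a median of -0.34 (adjusted p = 0.0017, and adjusted p = 0.27 with an estimated correlation). The cell cycle list fell in 1 of 36, with a median of -0.09 (adjusted p = 0.018, and adjusted p = 0.45 with an estimated correlation). Milk and alveolar differentiation fell in 6 of 19 and rose in 3, with a median of -0.07 and a mean of -0.70 (adjusted p = 0.030, and adjusted p = 0.44 with an estimated correlation).

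No scan day held DES 1 µg arrays of both ages. With scan day as a fixed block the medians were 0.56 for immediate early, 0.59 for macrophage, 0.29 for adipocyte, 0.26 for estrogen-responsive and -0.34 for endothelium genes, while milk and cell cycle turned to 0.08 and 0.01. The adipocyte, estrogen-responsive, milk and cell cycle calls ended (adjusted p = 0.073, 0.094, 0.073 and 0.61). Array signal as a covariate ended the estrogen-responsive and cell cycle calls (adjusted p = 0.051 and 0.21). Without array 1 or 2 of 35 days or array 1 or 2 of 49 days, 304, 134, 127 and 223 genes passed in place of 496. The cell cycle call ended without array 1 of 35 days (adjusted p = 0.25), and that of milk and alveolar differentiation without array 2 of 49 days (adjusted p = 0.067). Of 11 named genes 7 passed throughout (Prlr reached an adjusted p of 0.20). Glycam1 lost the call, as did Areg without array 1 or 2 of 49 days (adjusted p = 0.064 and 0.060) and Pgr without array 2 of 35 or array 1 of 49 days (adjusted p = 0.057 and 0.088). The split of 400 and 96 became 285 higher and 166 lower with 75th percentile scaling of all 12 arrays, 180 and 101 on the scanner files and 319 and 140 with quantile scaling.

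With DES 100 µg the milk genes rose with age instead. Csn1s2a was 14-fold and Wap 7.03-fold higher at 49 than at 35 days (log2 3.80 ± 0.25 and 2.81 ± 0.24, n = 2 arrays a group), and Csn2 rose by 1.70 ± 0.21. Aadat rose by 2.66 ± 0.22 and Igfals, part of the carrier of insulin-like growth factors, by 2.57 ± 0.23. Rgs4 (-3.91 ± 0.21), Tfpi (-2.65 ± 0.24), the smooth muscle actin gene Actg2 (-2.47 ± 0.13) and Pdlim3 (-2.03 ± 0.13) fell. Areg rose by 0.78 ± 0.13 (adjusted p = 0.014), and Pgr (0.32), Prlr (0.24) and Krt14 (-0.34) did not pass. In all 522 genes rose and 176 fell.

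Milk and alveolar differentiation rose with age under DES 100 µg in 9 of 19 (13 over the list alone). The milk median was 0.53 (camera adjusted p = 1.2e-07, and adjusted p = 0.087 with an estimated correlation). Lymphocyte genes rose in 5 of 11 (7), with a median of 0.77 (adjusted p = 0.00090, and adjusted p = 0.087 with an estimated correlation). Fibroblast and collagen matrix rose in 7 of 21, with a median of 0.47 (adjusted p = 0.0034, and adjusted p = 0.12 with an estimated correlation). Endothelium had a median of 0.46 (adjusted p = 0.0087, and adjusted p = 0.29 with an estimated correlation). Basal and myoepithelium was lower, with a median of -0.31 (adjusted p = 0.00087, and adjusted p = 0.087 with an estimated correlation). So was the cell cycle, at -0.28 (adjusted p = 0.00022, and adjusted p = 0.23 with an estimated correlation), and mast cell and eosinophil, at -1.09 (-1.0 at the bounds, adjusted p = 0.0084, and adjusted p = 0.12 with an estimated correlation). DNA damage and p53 stood at -0.19, immediate early and stress at -0.22 and interferon response at -0.26 (adjusted p = 0.0029 for each, and adjusted p = 0.29, 0.24 and 0.24 with an estimated correlation).

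No scan day held DES 100 µg arrays of both ages either. With scan day as a fixed block the medians were 0.63 for milk, 0.74 for lymphocyte, 0.46 for fibroblast, 0.45 for endothelium and -0.29 for basal genes. They were -0.36 for cell cycle, -0.92 for mast cell, -0.09 for DNA damage, -0.09 for immediate early and -0.04 for interferon genes. The calls of fibroblast, endothelium, DNA damage, immediate early and interferon genes ended (adjusted p = 0.065, 0.052, 0.16, 0.095 and 0.22). Without array 1 or 2 of 35 days or array 2 of 49 days, 223, 188 and 209 genes passed in place of 698. Of 10 named genes 9 passed throughout (Areg reached an adjusted p of 0.10). The endothelium call ended without array 2 of 49 days (adjusted p = 0.077), and the calls of mast cell and eosinophil and of immediate early and stress without array 1 of 49 days (adjusted p = 0.051 and 0.069). The split of 522 and 176 became 436 higher and 274 lower with 75th percentile scaling, 431 and 282 with quantile scaling, 295 and 183 on the scanner files and 291 and 222 with normexp.

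The DES 1 µg effect itself changed between the ages for 2468 genes, 1130 toward higher and 1338 toward lower values. The genes given here are the largest changes among named genes detected on every array of all 4 groups. Csn1s2a changed by -6.74 ± 0.35, Csn2 by -5.40 ± 0.30, Igf2 by -4.25 ± 0.16 and Wap by -4.0 ± 0.34 (n = 2 arrays in each of 4 groups, adjusted p = 0.00015, 0.00017, 3.5e-05 and 0.00095). Hpgd (4.76 ± 0.42), Atf3 (3.68 ± 0.17), Stc2 (3.47 ± 0.35) and Smim38 (3.08 ± 0.31) changed the other way. Prlr did so by 0.60 ± 0.17, while Pgr (0.42), Areg (0.38) and Krt14 (0.10) did not pass. The split of 1130 and 1338 became 1419 and 1050 with quantile scaling, and 859 and 1562 among genes detected on all 12 arrays.

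For DES 100 µg 1170 genes changed in effect between the ages, 550 toward higher and 620 toward lower values. Among named genes detected on every array of all 4 groups, Aadat (3.58 ± 0.31), Plat (2.46 ± 0.44), Hpgd (2.32 ± 0.42) and Pir (2.13 ± 0.37) led the first, and Pianp (-3.15 ± 0.73), Tcf3 (-3.06 ± 0.79), Slc13a3 (-2.78 ± 0.17) and Polm, a DNA polymerase (-2.70 ± 0.36), the second. Another probe of Tcf3 changed in the opposite direction without passing, so the direction for Tcf3 is not settled. Prlr (0.28), Areg (0.24), Csn2 (0.19), Pgr (-0.02) and Krt14 (-0.28) did not pass. The split became 735 and 449 with 75th percentile scaling, 643 and 448 with quantile scaling, and 382 and 784 among genes detected on all 12 arrays. Both changes of effect hold the oil arrays of 49 days. Leaving out 1 array gave 796 to 2953 genes for DES 1 µg and 295 to 863 for DES 100 µg. For DES 1 µg Prlr lost the call (largest adjusted p = 0.15), and for DES 100 µg Plat, Hpgd, Pir, Pianp and Tcf3 each lost it in at least 1 such fit (largest adjusted p = 0.14, for Tcf3). Array signal as a covariate ended the calls of Plat, Pir, Pianp and Tcf3.

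Among the probes in the authors' deposited tables of 2-fold differences, 406 were listed for DES 1 µg at 35 days, 203 higher and 203 lower, and 274 of the 376 that were tested here passed in the same direction (72.9%). The authors' deposited table for DES 100 µg at 35 days lists 121 probes, 39 higher and 82 lower, and 72 of 117 passed (61.5%). At 49 days the authors' deposited tables list 970 probes for DES 1 µg and 1023 for DES 100 µg, and 731 of 844 and 747 of 863 passed (86.6% each). These tables come from the same arrays, so they are no independent measurement.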

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

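Each result below was singled out because the effect of DES differed between 35 and 49 days by the interaction test in limma, for a gene count, a named gene or a gene list. Of the tests of explanations given here, those of scaling by the array median, of a distortion that goes with array signal, of lymphocytes and macrophages and of the share of epithelium were chosen after the result was seen, and those of signals close to background and of 1 animal before.

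For DES 1 µg the effect differed between the ages for 2468 genes. Toward higher values at 49 days the change was 4.76 for Hpgd, 4.49 for Gcnt3, 3.68 for Atf3, 3.47 for Stc2, 3.14 for Cxcl10, 3.08 for Smim38, 2.5 for Ier3, 2.14 for Pcp4, 2.07 for Fut2, 2.03 for Zbp1, 1.89 for Plat, 1.76 for Gadd45g, 1.75 for Irf7, 1.73 for Colec12 and 1.69 for Ccn1 on the log2 scale. It was 1.36 for Fcgr3a, 1.30 for Ogn, 1.14 for Fabp4, 1.06 for Adipoq, 1.04 for Cd74, 1.01 for C1qb, 0.93 for Usp18, 0.88 for Cma1, 0.78 for Vim, 0.60 for Prlr and 0.48 for Fcgr2b. Toward lower values it was -6.74 for Csn1s2a, -5.40 for Csn2, -4.25 for Igf2, -4.0 for Wap, -3.18 for Hoxb2, -3.12 for Caskin1, -2.98 for Ccdc33, -2.97 for Ecm1, -2.87 for Clca1, -2.58 for Pianp, -2.51 for Rps26 and -2.23 for Fabp3. Smaller falls were -1.91 for Csn3, -1.74 for Atp5mc1, -1.57 for Pttg1, -1.51 for Cox5a, -1.32 for Rasip1, -1.17 for Plk1, -0.86 for Sfrp2, -0.81 for Bgn, -0.70 for Cox5b, -0.58 for Lss and -0.57 for Rpl29. The sizes for Gcnt3 and Cxcl10 are less certain, since each was detected on 1 of the 2 oil arrays at 49 days. Genes not above background in oil at 35 or 49 days are given by adjusted p alone. Ifit3 (0.0037), Cpa3 (0.010), Cybb (0.0093) and Slc2a4 (0.0050) changed toward higher values, and Glycam1 (0.00087) toward lower.

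For macrophage and antigen presentation the DES 1 µg effect differed (median change 1.01, adjusted p = 2.3e-06, and 0.055 with an estimated correlation). So it did for immediate early and stress (0.83, adjusted p = 2.3e-06 and 0.13 likewise) and interferon response (0.77, adjusted p = 2.3e-06 and 0.13). Adipocyte (0.51, adjusted p = 0.0017 and 0.27) and mitochondrial oxidative phosphorylation (-0.48, adjusted p = 0.0047 and 0.48) were the other lists.

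For DES 100 µg the effect differed for 1170 genes. The change was 3.72 for Cxcl10, 3.58 for Aadat, 2.58 for Vsnl1, 2.46 for Plat, 2.32 for Hpgd, 2.13 for Pir, 2.13 for Cd3g, 2.12 for Jchain, 2.00 for Ifgga2l1, 1.94 for Atf3, 1.74 for Prelid3b, 1.58 for Col5a1, 1.53 for Pcp4 and 1.53 for Irf7. It was 1.35 for Fcgr3a, 1.33 for Ogn, 1.25 for Cd36, 1.18 for Loxl1, 1.16 for Trpc6, 1.15 for Vim, 1.15 for Aqp5, 1.06 for Fabp4, 0.98 for Xdh, 0.94 for Mgp, 0.81 for Cd74, 0.76 for Stat5a and 0.66 for Usp18. Toward lower values it was -3.15 for Pianp, -3.06 for Tcf3 (another probe of this gene has the opposite sign), -2.78 for Slc13a3, -2.70 for Polm, -2.64 for Rgs4, -1.30 for Clk1, -1.07 for Dlgap5, -0.81 for Cox5b and -0.80 for Atp5po. Cxcl10, Vsnl1 and Rgs4, detected on 1 of the 2 oil arrays at 49 days, have less certain sizes. By adjusted p alone, Ifit3 (0.0058), Erbb3 (0.014), Ccl7 (0.0015), Il2rb (0.0012) and Zap70 (0.017) changed toward higher fitted values. Pdlim3 (0.0051) and Glycam1 (0.0086) changed toward lower. For Erbb3 and Pdlim3 the direction is not established.

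Lists whose DES 100 µg effect differed, with the median change, were interferon response at 0.66 (adjusted p = 1.5e-06, and adjusted p = 0.17 with an estimated correlation), macrophage and antigen presentation at 0.61 (adjusted p = 9.6e-05 and adjusted p = 0.12 likewise), milk and alveolar differentiation at 0.56 (adjusted p = 0.0066 and adjusted p = 0.26), fibroblast and collagen matrix at 0.52 (adjusted p = 0.0042 and adjusted p = 0.18), duct growth factors and matrix remodelling at 0.50 (adjusted p = 0.023 and adjusted p = 0.23) and adipocyte at 0.43 (adjusted p = 0.0032 and adjusted p = 0.23). Wnt and Notch signalling changed by 0.35 (adjusted p = 0.026 and 0.26) and lymphocyte by 0.32 (adjusted p = 0.020 and 0.18). Ribosomal proteins changed by -0.44 (adjusted p = 0.0042 and 0.43). Cell cycle (adjusted p = 0.048 and 0.56) and mitochondrial oxidative phosphorylation (adjusted p = 6.3e-05 and 0.23) each changed by -0.47. Without oil array 2 of 35 days the calls of cell cycle, lymphocyte, duct growth factors and matrix remodelling, and Wnt and Notch signalling ended (adjusted p = 0.15, 0.078, 0.078 and 0.062).

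Every change above contains the oil arrays of 49 days, which stand apart from the rest. Scaling by the array median is not the whole cause, since 75th percentile scaling gave 4614 genes between the ages in oil. In the brightest of 4 equal gene groups 47.0% passed (964 higher, 78 lower), and 37.9% with that scaling (656 and 184). Signals near background are thus not the whole cause. A distortion that goes with array signal was tested on the dimmer minus the brighter array of 2 other groups, which correlated with 49 minus 35 days in oil at 0.595 across genes (35.4% of the spread shared). Such a distortion may thus account for part of the difference, age remains open as the biological cause, and with array signal as a covariate 1027 genes still passed.

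Interferon genes were higher in oil at 35 days than in the 5 other groups. If 1 animal were the cause, 1 array alone would stand high, but the lower of the 2 oil arrays exceeded the highest other array by 0.771, while the 2 oil arrays differed by 0.0631. More lymphocytes and macrophages in the dissected tissue would raise both lists. Both were higher in oil than with DES 100 µg at 35 days (0.456 ± 0.0864 and 0.704 ± 0.0957), where this cause remains open. The lymphocyte list was lower in oil at 35 days than with DES 100 µg at 49 days (-0.325 ± 0.0864). The values argue against 1 animal, and against more of both cell types as a cause common to every comparison. The macrophage list was higher in oil at 35 days than in each other group (0.105 to 0.708, each ± 0.0957), so more macrophages alone remain open. So do an effect of DES together with one of age in oil, and a cause common to both animals.

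Stromal markers were higher with DES 1 µg than in oil at 35 days and than with DES 100 µg at 49 days. A lower share of epithelium in the dissected tissue would raise the markers of every other cell type. At 35 days the macrophage list was lower instead (-0.708 ± 0.0957) while endothelium was higher (0.988), and at 49 days the lymphocyte list was lower with DES 1 µg than with DES 100 µg (-0.339 ± 0.0864). The luminal epithelium list does go with a lower share, at -0.379 ± 0.0832 with DES 1 µg at 35 days and 0.255 ± 0.0832 higher with DES 100 µg than with DES 1 µg at 49 days. A lower share alone would not lower the macrophage or lymphocyte list, but macrophages were high in oil at 35 days against every group. For the stromal markers a lower share remains open, as do more stromal cells of some types or a DES effect within them.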

How the results depend on the processing

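Of 4317 values for single named genes under an alternative, 3805 kept direction and side of the threshold, 450 lost the call, 26 gained one, 33 with no test moved and 3 reversed, and of 1228 values for gene lists 1024 kept both and 204 lost the call. The reversed values came from array signal as a covariate, chosen after seeing the data: Pitpnm1 at 0.11 with DES 100 µg at 49 days, and Fxyd7 at -0.42 and Pitpnm1 at -0.15 with age in oil. That covariate gave 1660 genes for DES 1 µg at 35 days, 2061 for DES 1 µg and 499 for DES 100 µg at 49 days, 1797 between doses at 49 days, 1027 for age in oil, 1895 for age with DES 1 µg, and 1176 and 659 for the changes of the DES 1 µg and 100 µg effects. The cause was not tested.

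A fit of the compared groups alone, which has 2 residual degrees of freedom in place of 6, gave 142 genes for DES 1 µg and 5 for DES 100 µg at 35 days, 1351 for DES 100 µg at 49 days, 197 and 104 between doses at 35 and 49 days, and 8 and 28 for age with DES 1 µg and 100 µg. A 2-fold difference with no test gave 291 for DES 100 µg at 35 days, 1666 and 1604 for the doses at 49 days, 2167 for age in oil and 1938 for the change of the DES 100 µg effect. Scanner signals with 75th percentile scaling gave 281 for age with DES 1 µg, and the cause was not tested. Without the dimmer array of DES 1 µg at 35 days and of DES 100 µg at 49 days, chosen after seeing the data, fewer arrays gave 380 genes for DES 1 µg at 35 days, 451 and 260 between doses at 35 and 49 days, 151 and 177 for age with DES 1 µg and 100 µg, and 1172 for the change of the DES 1 µg effect.

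Scan day as a fixed block on 10 arrays, added after the data were seen, leaves 1 residual degree of freedom. In limma it gave 0 genes in each of the 6 comparisons it can fit, and kept 0 of 103 calls of a named gene in a comparison. At an unadjusted p below 0.05 it gave 1321 and 1138 genes for DES 1 µg and 100 µg at 35 days, 1684 and 2393 between doses at 49 and 35 days, and 1020 and 1323 for age with DES 1 µg and 100 µg. As a random block, scan day gave 847, 104, 797, 1014, 367 and 543 in the same order, at a correlation of 0.217. Slide could not be run as a block.

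With the replicate number as a block, the counts were 1113 and 188 for DES 1 µg and 100 µg at 35 days, 4350 and 3517 at 49 days, 1224 and 1045 between doses at 35 and 49 days, 5480, 709 and 797 for age in oil, DES 1 µg and DES 100 µg, and 3157 and 1448 for the changes of effect, with 205 of 209 calls of a named gene in a comparison kept and 38 list calls. The labels do not pair arrays by that number, although for 10 of 12 arrays the closest array of another group has the same number and the pairing correlations lay between -0.12 and 0.43.

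Leaving out each array in turn, with the lone array left in a group assumed to vary like the other groups, gave 342 to 697 genes for DES 1 µg and 52 to 75 for DES 100 µg at 35 days, 1543 to 2177 and 1168 to 2473 at 49 days, 441 to 905 and 248 to 522 between doses at 35 and 49 days, 2718 to 3654, 127 to 304 and 188 to 771 for age in oil, DES 1 µg and DES 100 µg, and 796 to 2953 and 295 to 863 for the changes of effect. In the planned comparisons that hold the missing array, 4 to 18 gene list calls were made, since each such fit counts only those comparisons and calls also ended in them: 13 of 20 were kept without oil array 1 of 35 days, 4 of 7 without DES 100 µg array 1 of 35 days and 4 of 6 without DES 100 µg array 2 of 49 days. These fits hold fewer arrays.

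For gene lists, camera with an estimated correlation kept 5 of 36 calls in the planned comparisons, since it widens the error where the genes of a list vary together, and fry gave 57. Array signal as a covariate kept 29 of the 36. Beside those in the results it ended cell cycle for DES 100 µg at 35 days (adjusted p = 0.090), ribosomal proteins for DES 1 µg (0.39) and fibroblast for DES 100 µg (0.17) at 49 days, and ribosomal and mitochondrial for age in oil (0.63 and 0.40). A floor of 0.3, chosen after seeing the data, kept 32 and ended cell cycle for DES 100 µg at 35 days (0.051), macrophage for DES 1 µg (0.063) and duct growth for DES 100 µg (0.056) at 49 days, and immediate early for age in oil (0.061). Quantile scaling kept 29, and beside those in the results it ended mast cell for DES 1 µg and 100 µg at 35 days (0.074 and 0.068). No filter on detection kept 32, ending mast cell for both at 35 days (0.068 and 0.062), duct growth for DES 100 µg at 49 days (0.092) and immediate early for age in oil (0.067). With 75th percentile scaling of all 12 arrays, chosen after seeing the data, 33 were kept, and mast cell for both at 35 days (0.080 and 0.059) and macrophage for DES 1 µg at 49 days (0.051) ended. Without the dimmer arrays 12 of 14 were kept, and milk and fibroblast for DES 100 µg at 49 days ended (0.13 each). Signal over background limits what can be said of dim genes: 9588 probes were detected on all 12 arrays, and 2903 tested genes were not detected on both oil arrays of 49 days.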

Other observations

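Some genes were above background in 1 group of a comparison and not in the other, so that their difference has a lower bound and no size, and those named here were chosen after their values were seen. Sctr, the secretin receptor, was at least 13.5-fold lower with DES 1 µg than in oil at 35 days, and at least 41.3-fold higher with DES 100 µg than with DES 1 µg at that age. At 49 days it was at least 7.91-fold higher with DES 100 µg than in oil and at least 22.4-fold higher than with DES 1 µg. The chemokine gene Cxcl3 was at least 24.9-fold higher with DES 100 µg than with DES 1 µg at 35 days, and Ccl12 at least 7.37-fold lower with DES 100 µg than in oil. At 49 days, among genes that passed and were higher, 482 with DES 1 µg and 517 with DES 100 µg were detected on both arrays there and on neither oil array, of which 32 and 38 differed at least 2-fold by their bounds.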
